A study of Mus musculus with 12 samples.

How the data were processed

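RNA sequencing of 12 flash-frozen livers of female C57BL/6 mice (6 VPA, 6 VPA_OCA) was analysed from 1 table of the whole series, starting where the authors stopped. Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name edgeR, with no version, and the genome build GRCm38.p5; the aligner, the counter, the annotation and the use of strand are not given in the sources used here. Table columns were matched to samples by title, and 0 columns of per-sample values were left unused.

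The deposited values are normalized counts, per the file headers, a signal per gene made by dividing estimated read counts by a factor per library. In each library the low values cluster at multiples of 1 step (1.23 in VPA replicate 3, 0.559 in VPA_OCA replicate 1, 1.00 to 1.08 in the others). Of the values up to 20 steps, 79.8% to 84.4% lay within 0.1 of a whole multiple, so whole reads could not be recovered and no count model was used. The design written before the data were examined named a count test if the table held raw counts and limma on log2 values if it held normalized values, and the latter was used. The FPKM values of the authors equal the normalized count divided by gene length and column total (median ratio per library 0.9999 to 1.0001) and entered 1 alternative. The authors' table also gives p-values, adjusted p-values and log2 ratios, a GC fraction and a length per gene, per the file headers. Cells with a decimal comma and an exponent (238 p-values, 88 adjusted p-values, 10536 log2 ratios) were 1000 times too large and were divided by 1000; adjusted p-values recomputed over the 12517 genes the authors call present then differed from theirs by at most 0.538%. As written, 679 genes had an adjusted p under 0.05, and after this repair 697. The same repair was applied to the per-library values. A spreadsheet had also turned 26 symbols into dates, which were replaced through the gene ID. Of 34986 gene IDs, 34903 were found in GENCODE M21 (GRCm38), 33093 with the same start and end; positions printed are those of the authors' table.

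Genes with a normalized count of at least 1 in at least 6 libraries were kept (19006). Values were compared as log2(value + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, group as the only term) and Benjamini-Hochberg adjustment, with a threshold of 0.05. The 32 gene lists (530 entries, 523 in the table) were fixed before the data were examined and tested with camera (preset correlation 0.01, 2-sided, adjusted over the 32 lists). On simulated estimated counts with 19054 genes tested in the comparison of VPA_OCA with VPA, 41.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 8 false calls among 153. By camera, 1.5% of 200 random lists had p under 0.05. Each simulated gene was drawn independently, so that share does not hold for lists whose members move together. Changes were planted only in genes above a minimum mean, so recovery of low genes was not measured. Estimated depths were 17879222 to 37746632 reads, and with 6 libraries per group many changes of 1.5-fold lay below detection in that simulation. The 30 pairs of libraries within a group differed by 18.3 to 214 times the variance that sampling alone gives, so none was treated as a duplicate.

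Genes are named by a rule fixed beforehand: the 10 higher and 10 lower with the smallest adjusted p, leaving out unnamed models and pseudogenes; Nr1h4, Nr0b2, Abcb11, Slc51b, Cyp7a1 and Cyp8b1; up to 4 members of each list described, by p; and the 5 largest fold changes in each direction among genes past the threshold with a mean of at least 1 CPM. The alternatives chosen before the data were examined were other filters, scalings (median ratio, upper quartile), pseudocounts of 0.1 and 5, limma without trend or with array weights, a block for the replicate number, each library left out, thresholds of 0.10 and 0.01, an estimated correlation and fry. Added after the data were seen were a term for numbers 1 to 3 against 4 to 6, a loess correction for GC content (span 0.4), both together, each set of numbers alone, the authors' presence flag, total-count scaling, and leaving out 2 libraries with muscle transcripts. Principal components and the GC fit used the 11481 genes with a mean log2 value above 5. Figures were drawn with matplotlib 3.10.9. Lists of lipogenesis, cholesterol synthesis and other processes that are not described in the results were tested in the same way.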

Results

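Liver RNA of 12 female C57BL/6 mice aged 16 weeks was compared, 6 given valproic acid (VPA), an antiepileptic drug that can injure the liver, and 6 given VPA together with obeticholic acid (OCA), a bile acid derivative that activates the nuclear receptor FXR (VPA_OCA). The series concerns the role of FXR in liver injury by VPA, and the comparison asks which liver transcripts differ when the FXR agonist is added. Neither dose nor duration was given in the labels used here, and mice without VPA were not analysed here, so each difference is between VPA_OCA and VPA. Values are the authors' normalized counts, estimated read counts divided by 1 factor per library. They summed to between 20236900 and 22087711 per library. The commonest low value, taken as the worth of 1 read, gave estimated depths of 17879222 reads (VPA replicate 3) to 37746632 (VPA_OCA replicate 1), with the other 10 libraries between 19683964 and 22021646. Means are given ± SD with n = 6 per group, fold changes are on the scale of log2(normalized count + 1), which understates changes of low genes, and adjusted p-values are from limma-trend with Benjamini-Hochberg adjustment over 19006 genes unless another test is named.

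Addition of OCA was accompanied by higher transcript levels of 84 genes and lower levels of 53, 137 in all. The libraries also differed by replicate number, and with numbers 1 to 3 against 4 to 6 as a term, chosen after the data were seen, 254 genes were higher and 150 lower, 404 in all. The 53 became 26 in limma without trend and 28 to 49 with 1 library left out. The bile acid exporter subunit Slc51b was 9.24-fold higher in VPA_OCA and the sterol 12-alpha-hydroxylase Cyp8b1, which directs bile acid synthesis towards cholic acid, was 5.03-fold lower. The most significant rise was that of Ptgds, a prostaglandin D synthase, at 35.2-fold. The cell cycle regulator cyclin D1 (Ccnd1) and the drug efflux pump Abcb1a rose 2.59-fold and 2.58-fold. Among the genes that fell most were the transcription factor gene Tcf24, at 8.45-fold lower, and the zinc transporter Slc39a5, at 4.58-fold lower.

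**Figure D1:**
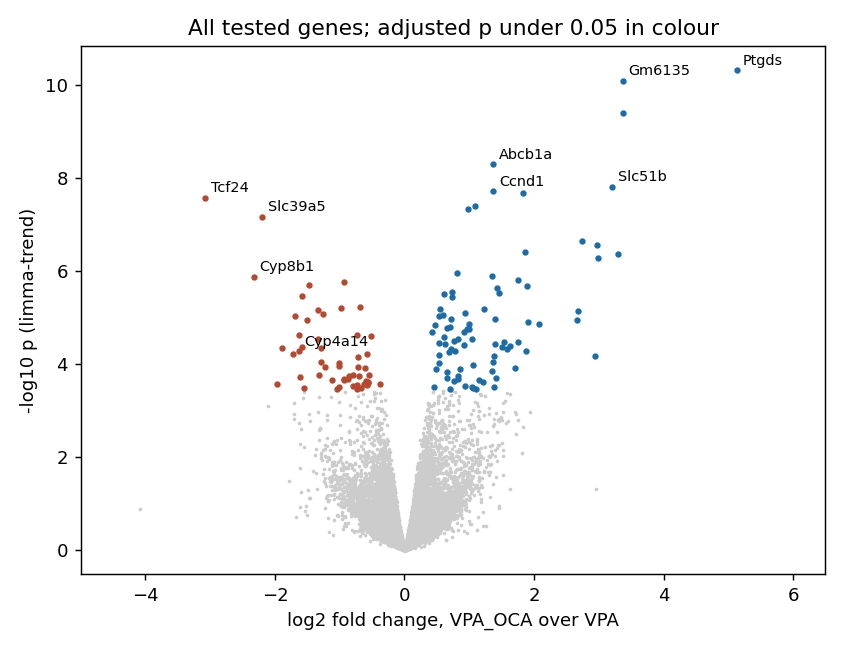
Log2 fold change of VPA_OCA over VPA (x axis) against -log10 of the limma-trend p-value (y axis) for the 19006 genes tested, 1 point per gene. The 84 genes that rose are blue and the 53 that fell are red; Ptgds lies farthest to the right at 5.14.

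Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046, GRCm38) went from 12.8 ± 6.34 normalized counts to 483 ± 161, with a log2 fold change of 5.14 ± 0.31 (SE) and an adjusted p of 7.7e-07 by limma. Its lowest VPA_OCA value, 182, lay above its highest VPA value, 24.2. Paxx, a DNA end-joining factor whose gene lies beside Ptgds on the same strand (chromosome 2, 25455141 to 25461094), rose from 211 ± 21.9 to 450 ± 57.6. Abcb1a rose from 274 ± 47.6 to 703 ± 66.3 and Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925) from 2424 ± 427 to 6257 ± 976. The other genes among the 10 with the smallest adjusted p were the water channel Aqp4 (3.54-fold), the glutathione transferase Gsta4 (1.98-fold), the collagen chain Col4a3 (6.67-fold), the organic anion transporter Slc22a7 (3.63-fold) and the dynein heavy chain Dnah1 (9.84-fold), the last from 1.39 ± 1.22 to 20.6 ± 6.76. Among the largest rises at a mean of at least 1 CPM were also the protease gene Tmprss4 (7.92-fold) and a pair of long non-coding RNAs on chromosome 3, Gm6135 (133789515 to 133791504) and Gm26691 (133830668 to 134240641). Gm6135 rose from 69.2 ± 17.3 to 744 ± 303 and Gm26691 from 7.97 ± 1.91 to 95.6 ± 38.0. Gm26691 overlaps the 5' part of Cxxc4 on the opposite strand, and whether counting used strand was not given in the sources used here. Cxxc4 itself did not rise, at 4.11 ± 1.97 in VPA and 2.79 ± 2.42 in VPA_OCA (limma adjusted p = 0.76).

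Tcf24 (ENSMUSG00000099032, chromosome 1, 9960163 to 9967932) fell from 70.0 ± 26.6 to 7.01 ± 2.0, and Slc39a5 (ENSMUSG00000039878, chromosome 10, 128395931 to 128401229) from 326 ± 55.0 to 74.7 ± 30.9. The other genes with the smallest adjusted p in this direction were the phosphatase Lhpp (1.91-fold lower), the vesicular glutamate transporter Slc17a8 (2.77-fold), Srgap3 (3.0-fold), the repressor Zhx3 (1.6-fold), the retinol saturase Retsat (1.97-fold), the transporter Slc16a13 (2.53-fold) and the fatty acid hydroxylase Cyp4a31 (2.40-fold). Akr1c18, a steroid dehydrogenase, and the dicarboxylate transporter Slc13a2 were 3.71-fold and 3.28-fold lower.

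The FXR gene itself and several genes that FXR is known to regulate did not pass the test. Nr1h4, which encodes FXR (ENSMUSG00000047638, chromosome 10, 89454234 to 89533585), measured 2746 ± 556 in VPA and 2250 ± 372 in VPA_OCA, with a limma adjusted p of 0.56. Nr0b2, which encodes the FXR-induced repressor SHP (ENSMUSG00000037583, chromosome 4, 133553376 to 133556536), measured 451 ± 167 and 849 ± 460, with a limma adjusted p of 0.57, and ranged from 208 to 1457 within VPA_OCA. It measured 451 ± 250 and 537 ± 286 within numbers 1 to 3 (n = 3 each, limma adjusted p = 0.89 within that set). Within 4 to 6 it measured 452 ± 87.5 and 1162 ± 394 (n = 3 each, limma adjusted p = 0.071). The bile salt export pump gene Abcb11 (ENSMUSG00000027048, chromosome 2, 69238282 to 69342616) measured 8930 ± 2809 and 12050 ± 3016, with a limma adjusted p of 0.53, but passed with the term for the numbers (limma adjusted p = 0.025). It measured 6474 ± 363 and 9553 ± 1777 within numbers 1 to 3 and 11387 ± 1220 and 14547 ± 943 within 4 to 6 (n = 3 each).

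Of the 17 tested members of the list of FXR-induced genes, 2 rose, none fell and 15 did not pass. Slc51b (ENSMUSG00000053862, chromosome 9, 65412714 to 65422955) rose from 19.1 ± 8.78 to 174 ± 44.6 normalized counts, with a log2 fold change of 3.21 ± 0.30 (SE) and a limma adjusted p of 5.7e-05. The aldo-keto reductase Akr1b7 rose from 127 ± 44.4 to 327 ± 134. The interleukin 1 antagonist Il1rn measured 179 ± 37.7 and 117 ± 30.8, and Apoc2 4229 ± 560 and 5548 ± 1164. Adjusted over the list alone, 3 members passed, Slc51b and Akr1b7 upwards and Il1rn downwards. The list as a whole had a median log2 fold change of 0.13 and did not pass camera (adjusted p = 0.075), but was called when VPA replicate 6 or VPA_OCA replicate 1, 2 or 3 was left out, with adjusted p from 0.016 to 0.048. With all 12 libraries it had an adjusted p = 0.67 with an estimated correlation. Without VPA_OCA replicate 4, 5 or 6 the list had camera adjusted p-values of 0.19, 0.22 and 0.12. Its median log2 fold change was 0.03 within numbers 1 to 3 and 0.33 within 4 to 6.

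In bile acid synthesis, 1 of 15 tested genes fell and 14 did not pass. Cyp8b1 (ENSMUSG00000050445, chromosome 9, 121914356 to 121916305) fell from 2484 ± 689 to 528 ± 252, with a log2 fold change of -2.33 ± 0.30 (SE) and a limma adjusted p of 0.0013. Cyp7a1, the rate-limiting enzyme of the classical pathway (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), measured 3915 ± 3046 in VPA and 3450 ± 2913 in VPA_OCA, with a limma adjusted p of 0.96. Cyp7b1, of the alternative pathway, measured 222 ± 43.2 and 160 ± 16.8. Adjusted over the list alone, 2 genes passed, Cyp8b1 and Cyp7b1, both downwards, and camera did not call the list (adjusted p = 0.36). Among 13 tested genes of bile acid and bile lipid transport, Slc51b alone rose and 12 did not pass, over all genes and adjusted over the list alone; Abcg5 measured 2849 ± 282 and 3470 ± 499 and Abcc4 156 ± 53.8 and 95.5 ± 28.2 (list adjusted p = 0.35 by camera).

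**Figure D2:**
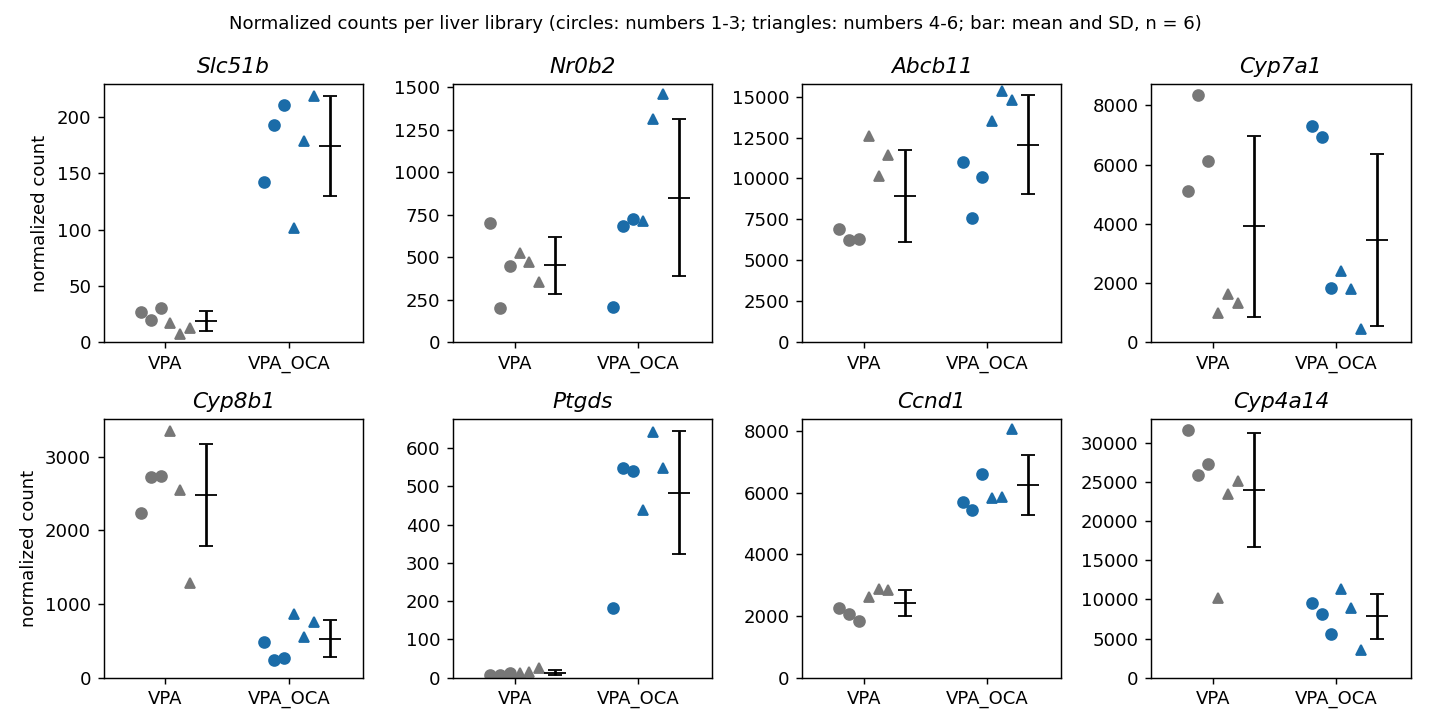
Normalized counts (y axis) of 8 genes in each of the 12 liver libraries, grey for VPA and blue for VPA_OCA, with circles for libraries numbered 1 to 3, triangles for 4 to 6 and a bar for mean ± SD (n = 6). The groups do not overlap for Slc51b, Cyp8b1, Ptgds and Ccnd1, while Cyp7a1 ranged from 974 to 8336 within VPA.

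Genes of fatty acid oxidation and ketogenesis lay lower in VPA_OCA, 27 of 29 with a negative log2 fold change and a median of -0.18. Of these, 2 fell and 27 did not pass, and adjusted over the list alone 6 passed, all downwards. The omega-hydroxylase Cyp4a14 fell from 23930 ± 7297 to 7832 ± 2830, a 3.09-fold difference, and its paralog Cyp4a31 from 531 ± 110 to 225 ± 74.2. Reads shared between related genes of this family could make the level of each uncertain, which was not tested. The thioesterase Acot1 measured 1937 ± 847 and 744 ± 432 and the trifunctional protein subunit Hadhb 5835 ± 868 and 4445 ± 550, and both passed over the list alone but not over all genes. Camera called the list lower (adjusted p = 1.8e-07), but its members moved together between libraries and the call was lost with an adjusted p = 0.67 when their correlation was estimated.

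Lipid droplet genes were also lower as a list (median log2 fold change -0.24, camera adjusted p = 0.0049), but not with an estimated correlation (adjusted p = 0.18), with 1 of 16 falling and 15 not passing. The droplet-forming protein gene Fitm1 fell from 169 ± 51.9 to 66.3 ± 22.2. Mogat1 measured 38.8 ± 20.4 and 11.02 ± 1.84, the droplet coat gene Plin4 342 ± 189 and 106 ± 67.7, and Fitm2 1461 ± 206 and 1158 ± 57.6. These 4 passed when adjusted over the list alone, all downwards.

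Of 20 tested genes of drug metabolism under the receptors CAR and PXR, 1 fell and 19 did not pass. Cyp2b9 fell from 9553 ± 1062 to 6372 ± 721. Cyp2b10 measured 195 ± 149 and 34.5 ± 11.7, a 4.30-fold difference that passed over the list alone but not over all genes. Adjusted over the list alone 2 genes passed, both downwards. Cyp2c29 and Cyp3a13 measured 1.24-fold and 1.29-fold lower without passing (list adjusted p = 0.075 by camera). Of 22 tested NRF2 and glutathione genes, Gsta4 rose, from 1170 ± 98.5 to 2327 ± 307, and 21 did not pass. Adjusted over the list alone 4 passed, all upwards: Gsta4, Gsta2 (780 ± 165 and 1420 ± 441), Nqo1 (251 ± 22.3 and 361 ± 75.7) and Gclm (2519 ± 466 and 3283 ± 286). With the term for the numbers these 4 passed over all genes, the last 3 with limma adjusted p-values of 0.016, 0.041 and 0.025. Camera did not call that list (adjusted p = 0.075).

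Of 24 cell cycle genes, Ccnd1 rose and 23 did not pass, with the same count adjusted over the list alone. Mcm2, Kif11 and Ccna2 measured log2 fold changes of 0.42, -0.39 and -0.49, and the list was not called (adjusted p = 0.35 by camera). Of 23 acute phase and inflammation genes, the acute phase glycoprotein Orm3 rose from 95.9 ± 34.0 to 354 ± 110 and 22 did not pass, also over the list alone; Hp, Lbp and Socs3 measured log2 fold changes of -0.39, -0.40 and 0.64 (list adjusted p = 0.40 by camera).

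**Figure D3:**
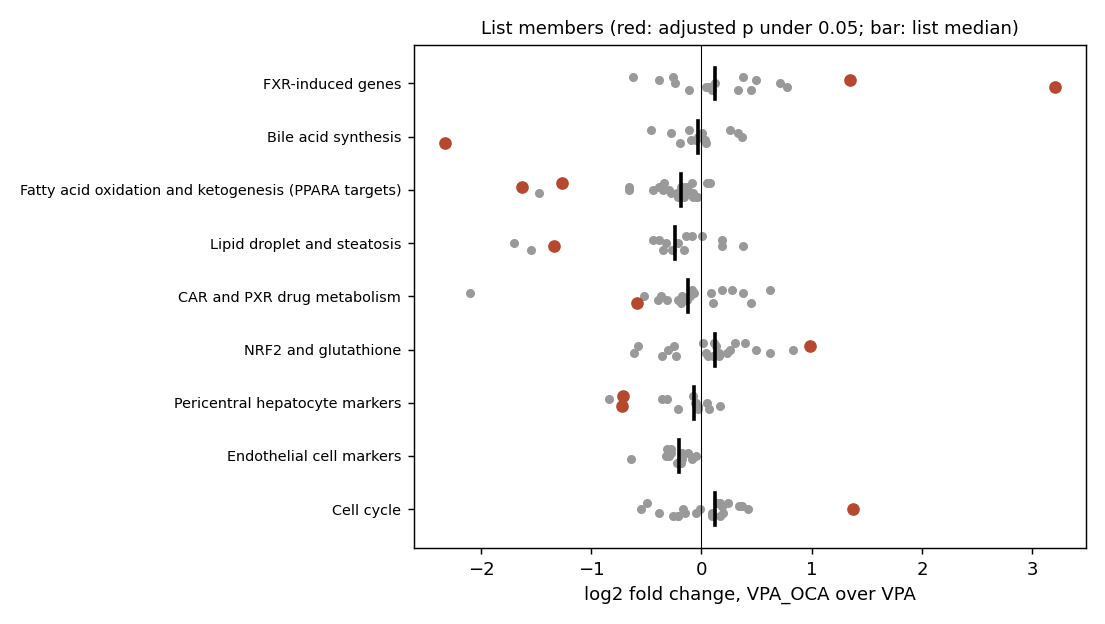
Log2 fold change of VPA_OCA over VPA (x axis) of each tested member of 9 gene lists, with members past an adjusted p of 0.05 in red and a black bar at each list median. The medians of fatty acid oxidation (-0.18) and lipid droplet genes (-0.24) lie below 0, and most members of every list are grey.

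Among marker lists, those of pericentral hepatocytes and of endothelial cells were lower in VPA_OCA by camera, but neither was called with an estimated correlation (adjusted p = 0.67 for each). In the pericentral list (median log2 fold change -0.07, adjusted p = 0.014), the glutamate transporter Slc1a2 fell from 3072 ± 335 to 1885 ± 356 and the ammonium transporter Rhbg from 155 ± 24.5 to 94.4 ± 16.4, and 12 of 14 did not pass. Oat measured 12525 ± 1692 and 7323 ± 2572 and Tbx3 546 ± 115 and 452 ± 139; adjusted over the list alone 3 passed, all downwards. In the endothelial list (median -0.21, adjusted p = 0.0042) all 14 log2 fold changes were negative, but the median was 0.05 within numbers 1 to 3 and -0.52 within 4 to 6. Of these genes none passed over all genes and Lyve1 alone passed over the list, at 164 ± 32.5 and 105 ± 23.5. Neither list was called without VPA replicates 4 and 5 (adjusted p = 0.075 and 0.30). The cholangiocyte list was not called (adjusted p = 0.27), although the epithelial cadherin gene Cdh1 rose from 244 ± 35.4 to 583 ± 251. Krt23 measured 129 ± 52.4 and 310 ± 190, and adjusted over the list alone these 2 passed. Their differences were larger in different sets of numbers. Cdh1 had log2 fold changes of 0.60 within 1 to 3 and 1.69 within 4 to 6, and Krt23 of 1.98 and 0.33. Krt19 and Cftr measured log2 fold changes of 0.50 and -0.55 over all libraries without passing. In the adipocyte list, also not called (adjusted p = 0.12), the carbonic anhydrase Car3 fell from 13747 ± 3994 to 7354 ± 1175 and was the 1 gene of 7 that passed, also over the list alone. Fabp4 measured 144 ± 43.4 and 114 ± 45.2, Adipoq 5.21 ± 7.82 and 3.21 ± 4.81, and Lipe 406 ± 171 and 364 ± 126, without passing. The fall of Car3 alone therefore does not show a change in adipocytes. The calls of Akr1b7, Slc1a2, Rhbg, Cdh1 and Car3 were lost when single libraries were left out, with limma adjusted p-values up to 0.103. Cdh1 lost its call without any 1 of VPA replicates 1 to 6 or of VPA_OCA replicates 4 to 6. Car3 did so without VPA replicate 1, 2, 3 or 5 or VPA_OCA replicate 3, 4, 5 or 6. Rhbg did so without VPA replicate 1, 4, 5 or 6 or VPA_OCA replicate 3, 4 or 5. Akr1b7 did so without VPA replicate 1, 2 or 3 or VPA_OCA replicate 1 or 3, and Slc1a2 without VPA replicate 3 or 6.

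Libraries differed in both groups by their replicate number. Along the first principal component, with 40.4% of the variance, those numbered 1 to 3 lay at or below -10.3 and those numbered 4 to 6 at or above 16.3. Mitochondrial transcripts made up 9.09% to 11.7% of the normalized counts in 1 to 3 and 5.84% to 7.51% in 4 to 6. The labels give no batch. The 404 genes that passed with this division as a term held all 137 above. Within numbers 1 to 3 (n = 3 per group) 121 genes passed, 64 of them among the 137. Within 4 to 6 (n = 3 per group) 95 passed, 45 of them among the 137. Slc51b had log2 fold changes of 2.76 and 3.65 in these sets, Cyp8b1 -3.02 and -1.64, and Ptgds 5.31 and 4.97. For Cyp8b1 the limma adjusted p within 4 to 6 was 0.066. Of the named genes that had not passed, 10 did so with the term: Abcb11, Gsta2, Nqo1 and Gclm as given above, Acot1 (limma adjusted p = 0.014), Mogat1 (0.015), Plin4 (0.0049), Cyp2b10 (0.0037), Oat (0.018) and Lyve1 (0.031). Cyp7a1 measured 6521 ± 1647 in VPA libraries 1 to 3 and 1309 ± 335 in 4 to 6, against 5353 ± 3055 and 1546 ± 1009 in VPA_OCA, and did not pass with the term (limma adjusted p = 0.81). The median log2 fold change of the fatty acid oxidation list was -0.27 within 1 to 3 and -0.13 within 4 to 6, that of the lipid droplet list -0.25 and -0.24, and that of the pericentral list -0.21 and -0.07. With a term for the replicate number itself as a replicate block, 210 genes passed. VPA replicates 4 and 5 also held skeletal muscle transcripts, such as Acta1 at 164 and 25.0 normalized counts; without both, 155 genes passed, 101 of them among the 137.

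**Figure D4:**
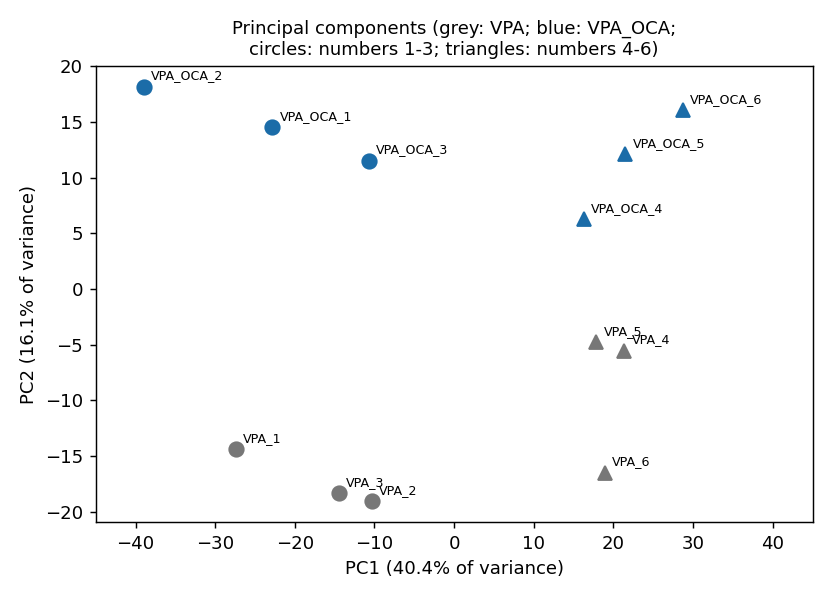
First and second principal components (x and y axes, in units of log2 normalized count) of the 12 libraries over 11481 genes with a mean log2 value above 5, grey for VPA and blue for VPA_OCA, circles for numbers 1 to 3 and triangles for 4 to 6. The first component (40.4%) parts the numbers and the second (16.1%) parts the groups.

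By the authors' deposited table, 697 genes had an adjusted p under 0.05, 418 higher and 279 lower, after repair of misread decimals, and 135 of the 137 genes found here were among them in the same direction. In the authors' deposited table Abcb11 had an adjusted p of 0.0073, Nr0b2 of 0.069, Nr1h4 of 0.15 and Cyp7a1 of 0.97.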

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

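The tests of GC content, of clock genes, of pericentral markers and of muscle transcripts below were chosen after the patterns had been seen; those of regrouping and of depth were fixed before their results were seen.

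A library stood far from the other 5 of its group in 9 of 154 groups of values, where chance gives about 1 in 20. Cyp2c70 measured 13140 normalized counts in VPA_OCA replicate 5, against 8558 to 10060 in the others. Cftr measured 6.15 in VPA replicate 3 and Adipoq 20.8 in VPA replicate 5. Krt19 measured 98.0 in VPA_OCA replicate 3, against 10.6 to 26.8. Gm26691 (168) and Gm6135 (1340) were both highest in VPA_OCA replicate 2. Tmprss4 measured 55.4 in VPA replicate 4 and Akr1c18 95.3 in VPA replicate 1. The estimated depth of VPA_OCA replicate 1, 37746632 reads, exceeded the 21130528 of the next library within VPA_OCA. Outside the genes tested above, Dmbt1 measured 1359 in VPA_OCA replicate 3 and at most 27.0 in any other library.

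The muscle transcripts Mb, Acta1 and Ckm measured 154, 164 and 127 normalized counts in VPA replicate 4 and 21.8, 25.0 and 21.8 in VPA replicate 5, and no more than 3.22 in the other 10 libraries. A candidate explanation is skeletal muscle in the piece of tissue. Of 27 other muscle transcripts, listed after some of their values were known, 22 were highest in VPA replicate 4, as muscle in the sample would give. Myh2 (8.12, against 6.21 in VPA replicate 4) and Neb (212 against 184) were highest in VPA replicate 5. Eno3, Tnnt1 and Tpm2 were highest in other libraries and measured 14.1 to 153 normalized counts throughout. No biological explanation was tested.

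The libraries numbered 1 to 3 differed from those numbered 4 to 6 in 4762 genes, 2441 of them higher in 4 to 6. This count is from a fit over both groups together with group as a term, so it does not show a difference within each group for every gene. A trend with GC content (Spearman correlation of 0.45 across genes, which are not independent) is not the whole cause, since 3801 genes still passed after each library's trend was removed. Depth is not the whole cause either, as 3489 passed without the deepest and the shallowest library. Time of day or feeding may have differed, but this stays open. After the GC correction 7 of 18 clock genes passed, among them Nr1d1, fewer than the 9 set as the mark. They were 4 higher and 3 lower in 4 to 6, while 3801 of all 19006 tested genes passed. Before that correction Dbp and Bhlhe41 were also higher in 4 to 6, by log2 differences of 0.83 and 1.77. Cry1 and Per2 were lower, at -1.04 and -0.49 (limma adjusted p under 0.05 for each). Nr1d1 and Arntl, set to move in opposite directions, were both higher in 4 to 6 after that correction, with log2 differences of 1.87 and 0.52 (limma adjusted p = 0.00014 and 0.15), and the labels give no time of collection. A difference in RNA quality was not tested. No biological explanation was tested.

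The genes of fatty acid oxidation and ketogenesis lay lower in VPA_OCA with a median log2 fold change of -0.183. A GC trend is argued against, since the fold changes hardly followed GC content (Spearman correlation of -0.03 over 11481 genes). For that reason the GC correction could move the list little. The median was -0.182 with the GC correction and the numbers as a term, and camera still called the list, although without these corrections its call was lost with an estimated correlation (adjusted p = 0.67). The fold changes followed gene length more (Spearman correlation of -0.18), which was not tested as a cause. A lower share of pericentral hepatocytes stays open. The pericentral markers had a median of -0.0685, with 11 of 14 below 0, less than the oxidation list but not beyond the bound set. That bound asked for a median above 0, so markers that merely stayed level could not have counted against this cause. The test therefore could not decide the question. Less PPARA-driven transcription with OCA may also contribute as a biological explanation and was not tested.

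Of 100 splits of the 12 libraries into 6 and 6, 3 gave at least the 137 genes found, the real one included. This is below the share of 0.05 set as the mark, so chance is unlikely by that mark but is not excluded. The others gave 482 and 312 genes and each set 5 libraries of the same numbers together, unlike the real split. The median over the 7 splits of that kind was 0 genes, so such a placement need not give many calls. Among 100 splits that kept numbers 1 to 3 and 4 to 6 balanced, 1, the real one, gave as many as its 404 genes, and the highest other gave 10.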

How the results depend on the processing

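The term for the numbers, the GC correction, the sets of numbers alone, the presence flag, total-count scaling and the omission of 2 muscle-bearing libraries were chosen after the data were seen. Of 75 named genes no direction was reversed past the threshold in any setting. Of the 34 that passed, 28 kept their call, at the threshold of 0.05, in every planned setting they were tested in and 6 lost it in some: Cyp4a14 without the trend (adjusted p = 0.056), and Akr1b7, Car3, Cdh1, Rhbg and Slc1a2 also when single libraries were left out, with adjusted p up to 0.072, 0.089, 0.10, 0.088 and 0.052. Of the 41 that did not pass, 7 gained a call at that threshold in some planned setting. Under the replicate block Acot1 (adjusted p = 0.025), Cyp2b10 (0.011), Mogat1 (0.022), Plin4 (0.00085), Gsta2 (0.0075) and Oat (0.016) passed, each also when certain single libraries were left out, and Fitm2 passed without VPA replicate 4 (0.0497). With array weights Acot1 (0.027), Mogat1 (0.041) and Oat (0.049) passed. The count of 137 genes stayed within 1.5 times under other filters, scalings, pseudocounts and weights and with each library left out (92 to 146). The genes that fell numbered 26 without trend, 29 within numbers 4 to 6 and 28 to 49 with 1 library left out, where 29, 28 and 29 were left without VPA replicates 2, 3 and 6 and 33, 31, 28 and 33 without VPA_OCA replicates 1, 3, 5 and 6. Under an adjusted p of 0.10 there were 223 genes (141 higher, 82 lower), and under 0.01 62 (46 and 16). Of the 34 named genes 25 also passed under 0.01 and 9 did not, Akr1c18, Cyp2b9, Slc13a2 and the 6 above; under 0.10 Mogat1, Cyp2b10, Gsta2 and Oat were gained.

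The replicate block gave 210 genes (129 higher, 81 lower). Whether the numbers pair the mice depends on the genes used: same-number correlations of deviations ran from 0.023 to 0.18 over all 19006 genes and from 0.15 to 0.48 over the 11481 higher ones, and 1 and 4 of 12 libraries correlated best with their own number. Libraries of different numbers within the same set of 3 correlated as much on average (0.13 and 0.34), against -0.13 and -0.33 across the sets, so these values do not show a pairing beyond the 2 sets. This check and the count under the block were seen together. The numbers as a term gave 404 genes (254 and 150), and with the GC correction 424 (259 and 165); the block changed no list call.

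With an estimated correlation no list was called: fatty acid oxidation, pericentral and endothelial lists had adjusted p = 0.67 each and lipid droplets 0.18. With fry the first 3 had 0.30, 0.30 and 0.55, and lipid droplets kept their call (0.030). Without both muscle-bearing libraries the pericentral and endothelial lists had 0.075 and 0.30, and the CAR and PXR list was called (0.0020). With 1 library left out the pericentral list ran from 0.0054 to 0.088 (0.088 without VPA replicate 5, 0.072 without VPA_OCA replicate 3) and the FXR-induced list from 0.016 to 0.22; the latter was called without VPA replicate 6 (0.048) and without VPA_OCA replicates 1 (0.016), 2 (0.040) or 3 (0.040). The lists of CAR and PXR drug metabolism, NRF2 and glutathione, cholangiocyte and adipocyte genes were also called without certain single libraries, with adjusted p down to 0.011, 0.023, 0.030 and 0.033. The cause of these differences was not tested.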

Other observations

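Further metabolic and transporter genes, chosen after their values were seen, also differed between the groups. Csad, an enzyme of taurine synthesis, fell from 922 ± 145 to 309 ± 128 normalized counts (n = 6 per group; limma adjusted p = 0.0045). The bile acid uptake transporter Slc10a2 rose from 71.7 ± 28.1 to 208 ± 70.3 (limma adjusted p = 0.010), the estrogen sulfotransferase Sult1e1 from 38.0 ± 14.4 to 132 ± 60.4 and the citrate transporter Slc13a5 from 10.5 ± 4.40 to 36.5 ± 16.7. Across the other 19 lists, lipogenesis and cholesterol synthesis among them, 0 of 273 members passed over all genes by limma, 7 passed adjusted over the list alone, and camera called 0 lists, with adjusted p from 0.075 for neutrophil markers to 0.98 for cholesterol synthesis and uptake. With the term for the numbers some of these members passed over all genes. Examples are Vldlr, which was lower (limma adjusted p = 0.0035), and Hal and Xbp1, which were higher (0.015 and 0.019).

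The genes that differed by replicate number formed groups too. Of 23 tested genes of cholesterol synthesis and uptake, 17 were higher in libraries 4 to 6 and 0 lower, with a median log2 difference of 0.72; camera called the list (adjusted p = 4.9e-07), though not with an estimated correlation (adjusted p = 0.66). Stellate cell, macrophage and endothelial markers also lay higher, with medians of 0.54, 0.45 and 0.38; camera called each, though not with an estimated correlation (adjusted p = 0.66 for each). The same held for lipogenesis, the unfolded protein response and the cell cycle, with medians of 0.48, 0.35 and 0.41 (camera adjusted p = 0.00042, 0.013 and 0.048; 0.66 for each with an estimated correlation). Mitochondrial DNA-encoded transcripts lay lower in 4 to 6, with a median of -0.47; camera called them (adjusted p = 8.8e-06), though not with an estimated correlation (adjusted p = 0.66), and after the GC correction the median was -0.07 and camera did not call them (adjusted p = 0.30). Nr1d1 differed by 2.06 ± 0.21 (SE) and the cold-inducible Rbm3 by -1.01 ± 0.08 on the log2 scale. The effect of OCA differed between the sets of numbers in 2 genes by an interaction term in limma, Gm21320 (adjusted p = 0.0074) and Map2k6 (adjusted p = 0.043). Of the 19006 genes, 1588 had an unadjusted interaction p under 0.05 by limma. Chance alone gives a share of about 0.05, so many of these need not differ between the sets. Gm21320 ranged from 218 to 960 in VPA 1 to 3, from 1655 to 29730 in VPA 4 to 6, from 0.0017 to 0.15 in VPA_OCA 1 to 3 and from 4854 to 21280 in VPA_OCA 4 to 6. Its values in VPA_OCA 1 to 3 lay below the worth of 1 read, so they are fractions of estimated reads. The level of Gm21320 and its interaction are therefore uncertain. Cyp2b10 averaged 63.6 ± 19.7 in VPA 1 to 3 and 326 ± 58.8 in VPA 4 to 6, against 31.1 ± 16.5 and 37.9 ± 6.17 in VPA_OCA (n = 3 each; interaction adjusted p = 0.37 by limma).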
